A study of Mus musculus with 2 samples.

How the data were processed

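Gene expression was measured on CodeLink Mouse Whole Genome Bioarrays, single-colour oligonucleotide arrays on which biotin-labelled antisense RNA is hybridised to one spot, or feature, per probe. Per the labels' protocols, total RNA came from bone marrow cells sorted by flow cytometry as negative for lineage markers and Flt3 and positive for Sca1 and cKit, a gate that enriches haematopoietic stem cells (HSCs), and was amplified repeatedly before labelling. There was 1 array of wild-type (+/+) mice and 1 array of mice heterozygous (+/-) for miR-125a that had a myeloproliferative disorder (MPD). Whether each RNA came from one mouse or from a pool is not given in the sources used here. Groups were taken from the genotype label of each sample.

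The values are normalized intensities on a linear scale, as deposited by the authors. The method of background correction and normalization is not given in the sources used here. The deposited value table held 36227 features on each array, from 0.001 to 30966, with a median of 28.8 on both. After sorting, the deposited intensities of the 2 arrays were equal to 5 decimals for 72.7% of positions and within 1% of each other for 99.6%, which is what quantile normalization leaves. Such normalization removes any difference between the arrays in overall brightness or in the shape of the distribution. The lowest value of 0.001 was shared by 747 features on the wild-type array and 857 on the heterozygous MPD array and carries no order.

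Features are identified in the value table only by a running number. The files used here do not pair these numbers with probes or genes, and the accession and symbol table at hand could not be matched to them. No gene is therefore named. The 33 gene lists fixed before the data were examined, the comparison of genes with a miR-125 seed match and the check of sex-linked genes were not run. The rule for named genes called for the 12 genes farthest apart each way among those with a symbol. In its place the 2 features farthest apart each way are given by number.

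A second deposited sheet held 2 columns of per-sample intensities without column or feature names. On inspection its rows repeated rows of the value table for part of the features, which may be those that are not controls. No reported value was taken from it and it did not select the features reported, because no column name ties it to a sample. The value table does not mark control spots or spots of poor quality, so all 36227 features were kept, and some of them may be controls.

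Differences are log2 of the intensity on the heterozygous MPD array minus log2 of that on the wild-type array. The files give no detection calls. For such files the rule written before the data were examined set the floor at each array's median over gene probes. Because control spots are not marked, the median over all features, 28.8 on each array, served as the floor instead. Differences were read for features above the floor on both arrays, and a difference of at least 2-fold was counted. For a feature above the floor on 1 array only, the brighter intensity was divided by the lowest intensity above the floor on the other array, which gives a lower bound. With 1 array per group there is no replicate error, and no test, standard error or p-value was computed for the difference between the groups. Shuffles and shifts of the feature order, used in the closing section, concern only how differences lie along the feature numbers. The number of arrays limits the precision. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6. The counting was tested on simulated data for this comparison, with 36227 features of which 120 were made higher. It recovered 113 of them when the change was 2.5-fold and all 120 when it was 4.0-fold. The simulated noise was narrower than the spread of the real differences, whose SD was 0.50. Only features above the median intensity were changed, and others of them were made lower. The recovery checks the counting and does not give its sensitivity on these arrays.

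The alternatives tried were a repeat of quantile normalization, removal of an intensity trend by loess, centring on the median, no floor, a floor at the 75th percentile, a pseudocount of 0.5 floors, and thresholds of 1.5-fold and 3-fold. A further 2 were chosen after seeing the data: removal of a running median over 501 feature numbers, and omission of features 3001 to 7500.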

Results

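The series compared HSC-enriched bone marrow cells of mice with both copies of miR-125a, a microRNA of the miR-125 family, with those of heterozygous mice that had developed an MPD, a disorder in which myeloid blood cells are overproduced. Each group was represented by 1 array. Genotype and disease went together, since the heterozygous sample came from mice with the disorder, so the comparison does not part one from the other. All differences given here are between these 2 arrays and have no replicate error. The 36227 array features carry numbers but no gene names in the files used here. For this reason the sorting markers Kit, Ly6a (which encodes Sca1) and Flt3 could not be read, and no blood lineage or pathway was scored. The targeted microRNA could not be read either, and whether the array probes it is not given in the sources used here.

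Most features had similar intensities in the wild-type and the heterozygous MPD cells. Of the 16372 features above the floor on both arrays, 15627 (95.4%) differed by less than 2-fold. The heterozygous MPD array was at least 2-fold higher at 475 features (2.90%) and at least 2-fold lower at 270 (1.65%). Higher features made up 63.8% of the 745 features at this threshold. The middle of the distribution lay slightly below 0, with a median log2 difference of -0.03, quartiles at -0.29 and 0.24, and 5th and 95th percentiles at -0.71 and 0.81. The SD of the log2 difference across features was 0.50. Across features, which are not independent replicates, the log2 intensities of the arrays correlated with a Pearson r of 0.968 and a Spearman rho of 0.947.

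**Figure D1:**
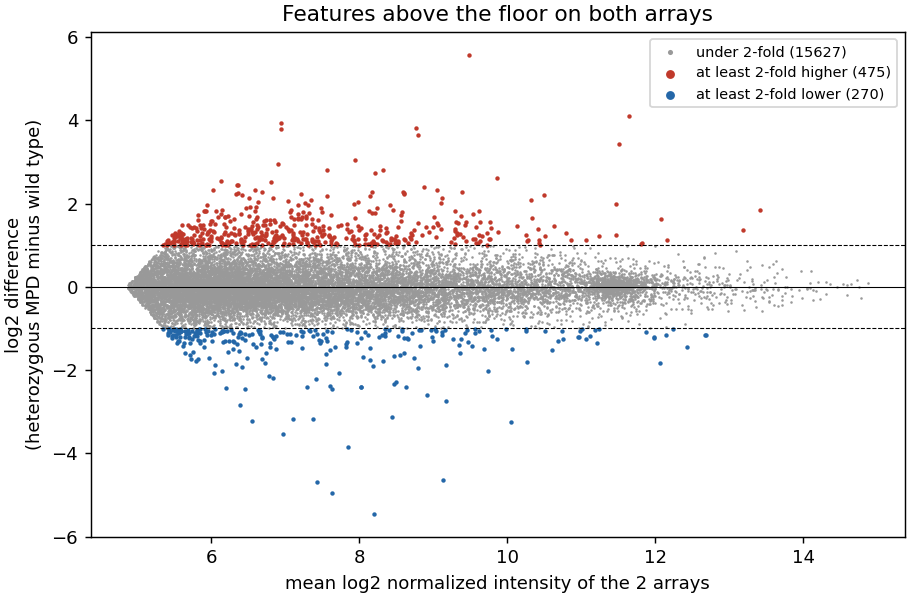
Log2 difference (heterozygous MPD minus wild type) against the mean log2 normalized intensity of the 2 arrays, one point per feature above the floor on both arrays, with dashed lines at 2-fold. The 475 features at least 2-fold higher and the 270 at least 2-fold lower lie on either side of 15627 features with smaller differences.

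The balance of higher and lower features depended on the size of the difference. At 1.5-fold the counts were close, with 1559 features higher and 1383 lower. At 3-fold 109 features were higher and 58 lower, and at 4-fold 44 were higher and 31 lower. At 8-fold 8 features were higher and 11 lower, too few to tell a turn from an even split. The balance at 2-fold was also read by brightness. Among the 6719 measured features with a geometric mean intensity under 100, 180 were at least 2-fold higher and 112 lower. Between 100 and 500 the counts were 222 and 103 of 5932 features, and between 500 and 2000 they were 61 and 38 of 2190. Among the 1531 features of 2000 and above 12 were higher and 17 lower, again too few to tell a turn from an even split. Control spots are not marked, so any among the features are counted in these ranges and in the totals. The larger count of lower features among the brightest may rest on features that the second deposited sheet leaves out.

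Among features above the floor on both arrays, the feature farthest up, number 19152, had a normalized intensity of 104 on the wild-type array and 4946 on the heterozygous MPD array, a log2 difference of 5.57 or 47.5-fold. Feature 20435 followed with 776 and 13281, a log2 difference of 4.10 or 17.1-fold. The feature farthest down among them, number 15628, had 1943 on the wild-type array and 44.3 on the heterozygous MPD array, a log2 difference of -5.45. Feature 16475 had 1101 and 35.8, a log2 difference of -4.94. The dimmer values of both features that were lower lay close above the floor of 28.8, whereas feature 20435 was far above it on both arrays.

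A further 1741 features lay above the floor on the heterozygous MPD array only, and 1741 on the wild-type array only. Equal numbers follow from floors set at the median of each array. By their lower bounds, 176 of these features were at least 2-fold higher on the heterozygous MPD array and 130 at least 2-fold lower. The largest bounds were at least 85.8-fold higher and at least 92.6-fold lower.

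Measured differences were not spread evenly over the feature numbers. Among the 2310 measured features numbered 3001 to 7500, a stretch chosen after the values were seen, 55 were at least 2-fold higher and 82 at least 2-fold lower on the heterozygous MPD array, with a median log2 difference of -0.14. Among the other 14062 features 420 were higher and 188 lower, with a median of -0.02. Features at least 2-fold lower made up 3.55% of those measured in the stretch and 1.34% of those measured elsewhere. The stretch was not uniform, since its block from 7001 to 7500 had a median of -0.0056, and it was not the only low part, since the block from 31001 to 31500 had a median of -0.21.

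**Figure D2:**
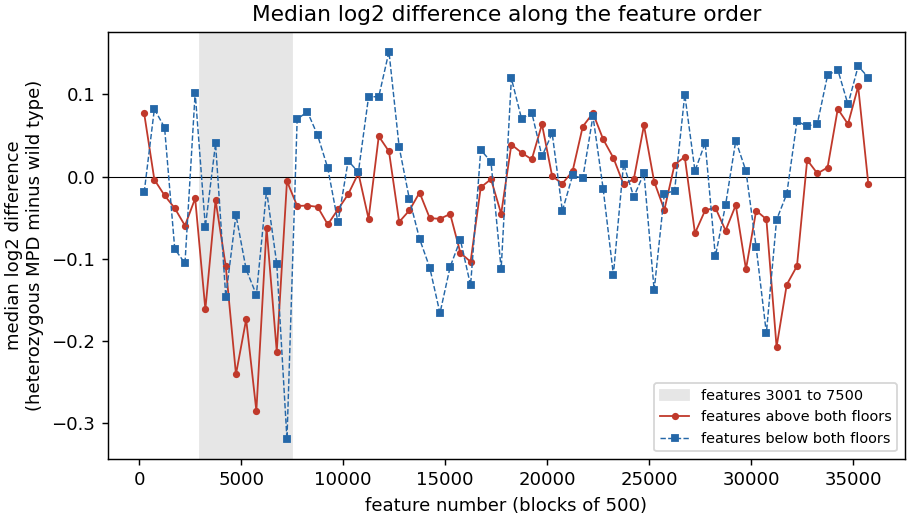
Median log2 difference (heterozygous MPD minus wild type) in 72 consecutive blocks of 500 feature numbers, for features above the floor on both arrays and for features below it on both with intensities over 5. Among features above the floor, the shaded stretch from 3001 to 7500 holds the lowest block median, -0.28, and the highest block median is 0.11.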

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

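Over 10 other settings the higher features outnumbered the lower ones at the threshold used. The 4 numbered features kept their direction under each setting that gave them a value, which the 75th-percentile floor did only for feature 20435. The counts of features at least 2-fold higher and lower were 475 and 270. They became 4193 and 3793 with no floor (features at 0.001 still left out), of which 52.5% were higher. They were 182 and 107 with a floor at the 75th percentile, where the bounds gave 62 higher and 33 lower. With a 1.5-fold threshold they were 1559 and 1383 (52.99% higher), and the bounds gave 480 and 448. With a 3-fold threshold they were 109 and 58, and the bounds gave 51 and 26. A pseudocount of 0.5 floors left 346 higher and 177 lower. The higher share was 68.6% after loess, 68.3% after centring, 70.6% after removing the running median and 69.1% without features 3001 to 7500, the last 2 settings chosen after seeing the data. Centring could only raise the share, as the median lay below 0, and so could omitting features picked for their lower values. A higher floor or threshold keeps fewer features by construction, and other causes were not tested. Repeating quantile normalization moved almost nothing, as the deposited values already shared one distribution. The correlation ranged from 0.897 to 0.971. Raw intensities and probes averaged per gene were not run, because the files used here hold no raw values and no gene names tied to the feature numbers. The second sheet was inspected but not used as a source, since its columns have no names. No paired analysis was possible because each group had 1 array.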

Other observations

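Loess and centring were planned settings, and their use on these patterns and the other tests in this part were chosen after the result was seen. Features numbered 3001 to 7500 were lower on the heterozygous MPD array, with a median log2 difference of -0.14 against -0.02 elsewhere, although the block from 7001 to 7500 lay at -0.0056 and a block outside, from 31001 to 31500, at -0.21. The SD of the medians of 72 blocks of 500 numbers was 0.074, above the highest of 1000 shuffled feature orders at 0.038. A trend with intensity is argued against, since after loess the difference between the stretch and the rest was still -0.12 on the log2 scale. An uneven signal along the feature order of one array is a candidate explanation: block medians of features above both floors and of dim features below both floors correlated across the 72 blocks (Pearson r = 0.459, Spearman rho = 0.542), and none of the other shifts of the block order gave so high an r. Single blocks did not always go together: block 7001 to 7500 had a dim median of -0.32, and block 31001 to 31500 one of -0.05. The r was 0.442 without the 2 blocks farthest from the median and 0.432 outside the stretch, but a grouping of probes by kind along the numbers stays open, because the numbers could not be tied to genes or positions.

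More features were at least 2-fold higher than lower on the heterozygous MPD array (63.8% of 745). The surplus remained after loess (68.6%) and after the running median was removed (70.6%). Both steps also recentred the differences, which by itself pushes the share up. The rise therefore decides nothing about a trend with intensity or uneven signal along the feature order. Neither step gave a share below that of centring alone, but a part played by either cause stays open. Centring on the median, which gave 68.3%, decides nothing, because its direction was fixed by a median below 0. The deposited values of the 2 arrays shared nearly one distribution, with a median of 28.8 on both, which leaves no overall offset in brightness. The median log2 difference of -0.03 is therefore no separate evidence on a uniform scaling offset. Also open are the 2 RNA amplifications, any unmarked control spots, differences between single samples, and the genotype or disease. With 1 array per group there is no replicate error to tell these apart. Genotype and disease went together, so the comparison cannot part one from the other.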
